A study of Mus musculus with 56 samples.

How the data were processed

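RNA was measured in gastrocnemius, a calf muscle, of female C57BL/6J mice kept in 12 h of light and 12 h of darkness. Per the labels' protocols, the mice had 7 days of free feeding before 7 days of food restricted to the light phase (daytime-restricted feeding, DRF) or to the dark phase (nighttime-restricted feeding, NRF), and were 9 weeks old at collection. Tissue was flash frozen, RNA was extracted with Trizol, and polyadenylated RNA was selected on oligo(dT) beads and copied from random hexamers. The libraries were read on a BGISEQ-500 as paired ends of 100 bases. The protocol names no step that marks the strand, so reads of a gene and of an antisense partner cannot be told apart. The submitters' processing notes name HISAT2, Bowtie2 and RSEM, with the builds mm10 and GRCm38.p6. Their versions, their roles and the annotation are not given in the sources used here.

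The authors deposited a table of 19072 genes by 56 libraries headed as TPM, and a table per regimen of their own rhythm tests. The values headed TPM are a score rather than TPM. They were read as following the formula K × log2(1 + 1000000 × c / N) / L. Here c is an estimated read count with 2 decimals, N a library size, L a whole-number gene length, and K the factor that makes each column sum to 1000000. The table that resulted is compressed by the logarithm and divided by length, so it is no linear abundance. The formula was inverted gene by gene, from 291 calibration genes outward. A solution was accepted where 90% of a gene's values above 0 lay within 0.02 of a whole read or, for genes with decimal counts, within 0.1 of a step of the second decimal. The formula rests on c meeting the whole-read rule in 10626 of the 12025 genes tested below, with L chosen gene by gene to meet it. Run forwards on c rounded to 2 decimals, it returned every value of these 12025 genes within a relative deviation of 0.00015. Since c came from inverting the same formula, that deviation measures rounding and does not test the formula. Estimated counts were recovered for 17443 genes. Another 1629 genes had fewer than 4 values above 0 (607 of them had none) and were left out. The inversion was tested on 6000 genes simulated with the same formula, which checks the inversion and not the formula. In the 2643 with a mean of 30 reads or more it returned 100% of lengths exactly and, where a solution was accepted, 100% of counts. Genes with decimal counts share reads with other genes, often near-identical copies, and are named below as uncertain. They are 1399 of the 12025 genes tested, and a further 148 tested genes allow more than 1 length. Gene symbols and GRCm38.p6 coordinates came from the reference annotation by gene ID (18955 IDs had a symbol).

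The recovered totals were 28173235 to 36183625 reads per library. The authors' library sizes N, fixed by the deposited scores, were 0.854 to 1.21 times those totals, and how they were derived is not given in the sources used here. CPM were computed as recovered counts per 1000000 of N, and tests were run on log2(CPM + 1). The design fixed before the data were examined had assumed TPM and a test on log2(TPM + 1) with a mean TPM of at least 1. The unit was changed to CPM and the rest of the design was kept. Folds are on the log2(CPM + 1) scale, which understates the change of low genes. No column of the deposited tables was left unused.

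Genes with a mean CPM of at least 1 over all libraries were fitted with limma (version 3.58.1, lmFit and eBayes with a mean-variance trend) in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg over the 12025 genes with a threshold of 0.05. All 14 groups entered each fit. DRF was compared with NRF at each of the 7 zeitgeber times (ZT, hours from lights on) and on average over the day, where ZT0 and ZT24 together counted as 1 time. Rhythm was fitted by a cosine and a sine of 24 h with an intercept per regimen. Peak times and peak-to-trough values below are those of this fitted curve, which does not follow a transcript with more than 1 high in a day. Moderated F tests asked whether both terms were 0 in a regimen, and whether they were equal in DRF and NRF. ZT24 was compared with ZT0 within each regimen. Intervals for the core clock genes and list scores are 95% bootstrap intervals from 2000 resamples of the libraries within groups. With 4 libraries per group such intervals tend to be too narrow. A list score is the mean over members of the log2 value minus the gene's own mean.

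Members of 26 gene lists were counted over all genes and adjusted over the list alone. The lists were core clock, lipid droplet and lipolysis, fatty acid uptake and oxidation, PPAR fasting targets, FoxO and atrophy, glycolysis and glycogen, oxidative phosphorylation, fatty acid synthesis, cholesterol synthesis, glucocorticoid targets, heat shock, cold-inducible, endoplasmic reticulum stress, amino acid response, ribosome biogenesis, immediate early, slow fibre, fast fibre, extracellular matrix, satellite cell, endothelium, macrophage and leukocyte, red blood cell, adipocyte, brown adipocyte, and nerve and Schwann cell. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. The share of members whose rhythm differed was tested against all other genes by Fisher's exact test (two-sided), adjusted over the 26 lists. That test counts genes as independent, but members of a list were measured in the same libraries and can vary together. Its p-values can therefore be too small. Genes were named by a rule. On average over the day it took the 10 higher and 10 lower genes with the largest difference, a mean CPM of at least 5 and the same sign at all 7 times. For rhythm it took the 10 with the largest peak-to-trough in each regimen and the 10 whose cosine and sine terms differed most. It took 3 higher and 3 lower genes at each time, 5 and 5 for ZT24 against ZT0, every core clock gene, and up to 4 members of each other list by smallest p. Not every result of the rule is reported here. Predicted and clone symbols, mitochondrial and histone genes and pseudogenes were not named, and the rule as run also passed over LOC symbols and IDs with no symbol.

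Per the file headers, the authors' rhythm tables combine JTK and Lomb-Scargle tests at a period of 24 h into a p-value and a q-value (adjusted p), with a phase, a base level and an amplitude. The gene tests were checked on simulated data with 200 changed genes. For a difference of 0.5 log2 units they recovered 97.0% on average over the day and 55.2% at ZT16. For a peak-to-trough of 0.5 they recovered 76.1% for a rhythm in DRF alone. The test of the rhythm difference recovered 88.1% where both regimens had such a rhythm with nearly opposite peaks. Over all sizes simulated together (0.25, 0.5 and 1), the 4 tests made 195, 115, 141 and 161 calls. False calls made up 8.72%, 4.35%, 7.80% and 4.97% of them. On average over the day and for the DRF rhythm this was more than the intended share of 5 in 100. Each share came from a single simulated run and carries its sampling error. Each simulated gene was drawn independently. The real libraries also vary together across genes, so these rates need not hold for them. Replicates 1 to 4 of a group differed by more than counting noise in all 84 pairs (chi-square per degree of freedom 4.31 to 37.9 over 10471 genes), so no library counted as a duplicate. The labels number the replicates but do not say that each is a separate animal, and the p-values then measure only the spread between these samples.

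Alternatives fixed before the data were examined were another pseudocount, other filters, median-ratio and quantile scaling, library weights, a replicate block, equal weights for the 7 times, ZT0 or ZT24 left out, a 12 h harmonic, F tests over the 7 times in place of the cosine fit, the authors' adjusted p and each library left out in turn. The others were chosen after seeing the data: log2 of the deposited value plus 1, limma's voom weights, total-count scaling, slow-fibre and adipocyte scores as covariates, removal of each library's trend with gene length, 2 outlying libraries left out, and the first 2 components of the deviations from group means as covariates. These are called within-group components below, and they come from the same values that are then tested. Other software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and the R package data.table (1.17.8).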

Results

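Gastrocnemius muscle was sequenced from mice fed only in the light phase (DRF) or only in the dark phase (NRF), the phase in which mice are normally active and eat. NRF was the reference. Muscle was taken at ZT0, ZT4, ZT8, ZT12, ZT16, ZT20 and ZT24 in each regimen, with 4 libraries in each of the 14 groups and 56 libraries in all. The libraries held 28173235 to 36183625 recovered reads. The 10 most abundant genes took 19.5% to 32.8% of a library's reads. Levels below are CPM, the recovered read counts per 1000000 of the authors' library size, given as mean ± SD over 4 libraries.

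The main question was which daily transcript rhythms of muscle followed the inverted feeding time. Transcripts of fuel use in fasting had a far larger daily rhythm under DRF. Pdk4 (gene 27273, chromosome 6, 5483351 to 5496278), whose product restrains pyruvate dehydrogenase and so spares glucose, stood at 28.1 ± 6.60 CPM at ZT12 and 2891 ± 1231 at ZT24 in DRF (n = 4 each), against 303 ± 172 and 491 ± 524 in NRF. Its fitted peak-to-trough was 6.24 log2 units in DRF (75.6-fold), with a peak at ZT22.7, and 1.05 in NRF, where the rhythm test was missed (adjusted p = 0.54). Ucp3 (22229, chromosome 7, 100472991 to 100486432), a mitochondrial carrier induced by fasting, went from 23.3 ± 4.10 CPM at ZT12 to 320 ± 123 at ZT0 in DRF, and was 77.2 ± 33.3 and 78.8 ± 54.1 in NRF. Angptl4 (57875, chromosome 17, 33774900 to 33781575), a secreted inhibitor of lipoprotein lipase, reached 41.6 ± 19.6 CPM at ZT24 in DRF and 3.25 ± 2.71 in NRF.

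**Figure D1:**
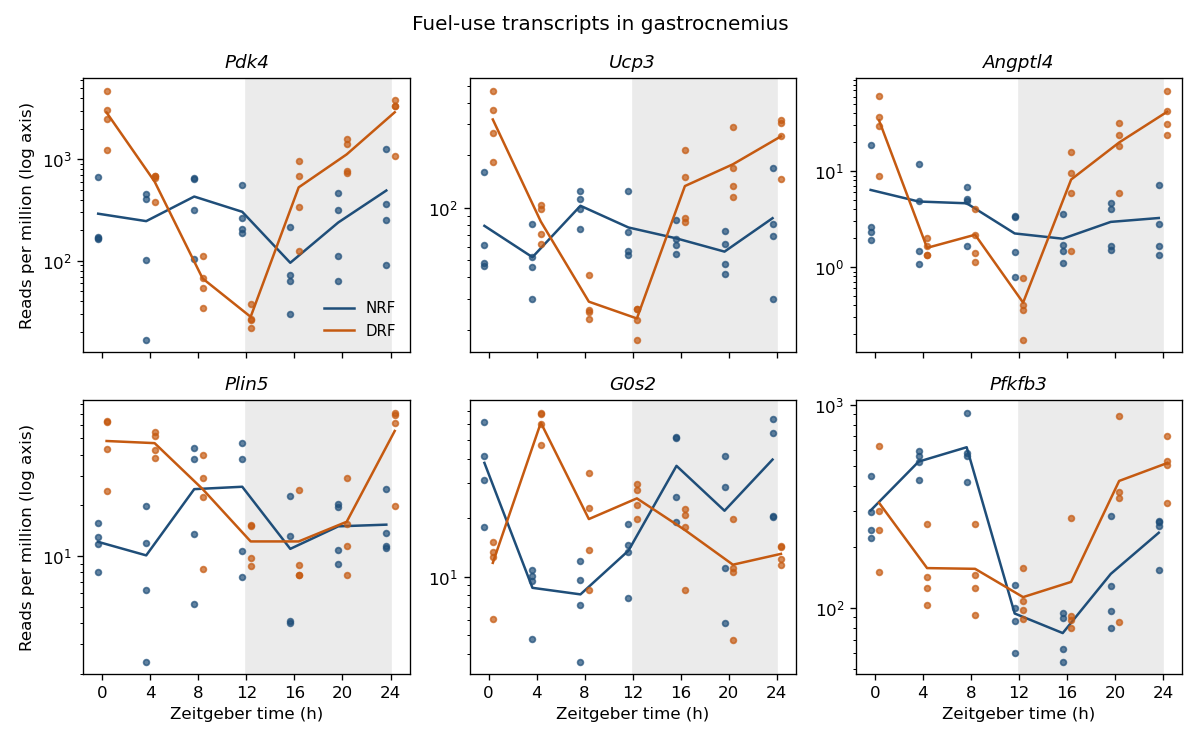
CPM (log axis) of 6 fuel-use transcripts against zeitgeber time in hours, with a point per library, lines through the group means (NRF blue, DRF orange) and the dark phase shaded. Pdk4 in DRF runs from 28.1 CPM at ZT12 to 2891 at ZT24, while G0s2 and Pfkfb3 differ most by day, at ZT4 (61.2 in DRF and 8.75 in NRF) and ZT8 (156 and 619).

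A test of the rhythm itself, whether the cosine and sine terms were equal in both regimens, passed for 1578 of 12025 genes (13.1%). The peak-to-trough was larger in DRF for 1089 of them and larger in NRF for 489. Pdk4 (adjusted p = 1.77e-06), Angptl4 (2.09e-05) and Ucp3 (2.57e-08) were among the 10 genes whose rhythms differed most. Another was Slc25a34 (384071, chromosome 4, 141618819 to 141623891), a mitochondrial carrier with a peak-to-trough of 3.08 in DRF and 0.59 in NRF (adjusted p of the difference 0.00329). Chac1 (69065, chromosome 2, 119351242 to 119354326), which degrades glutathione and responds to amino acid shortage, peaked at ZT19.7 in DRF with a peak-to-trough of 2.94, against 1.27 in NRF (0.000133). For 3 others the fitted peak moved between day and night. G0s2 (14373, chromosome 1, 193272160 to 193273188), an inhibitor of triglyceride breakdown, had a fitted peak at ZT20.0 in NRF and ZT7.27 in DRF (adjusted p of the difference 0.000623), while its highest means stood at ZT24 in NRF and ZT4 in DRF. Pfkfb3 (170768, chromosome 2, 11471430 to 11554071), which makes an activator of glycolysis, peaked at ZT4.62 in NRF and ZT23.1 in DRF (0.000117). Pck1 (18534, chromosome 2, 173153073 to 173159274), an enzyme of glyceroneogenesis, peaked at ZT11.3 in NRF and ZT20.6 in DRF (0.00165, and 0.00216 with the adipocyte score as a covariate). Pck1 is also a member of the adipocyte list, whose score had a peak-to-trough of 1.15 in NRF (95% interval 0.72 to 1.69) with a peak at ZT13, and 0.57 in DRF (0.13 to 1.36) at ZT16.8. Cyp2e1, an oxidase, peaked at ZT12.7 and ZT20.1 (0.00283). Arrdc2, an arrestin-like gene, had a peak-to-trough of 4.17 in NRF and 1.99 in DRF (0.0157), and this call ended with ZT0 or ZT24 left out (adjusted p up to 0.232). The count was 1017 without ZT24, 2592 with within-group components as covariates and 2687 with library weights.

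Lists of fuel metabolism held most of the lists whose members differed in rhythm more often than other genes did (13.1% of genes outside a list). Fisher's exact test makes no allowance for members that vary together, so its p-values here and below can be too small. Of the PPAR fasting targets, which burn or spare fuel when food is absent, 8 of 14 differed, and 10 when adjusted over the list alone (Fisher's exact test, adjusted p = 0.00162). In NRF 2 of these 14 passed the rhythm test and in DRF 10 did. Their score had a peak-to-trough of 0.21 log2 units in NRF (95% interval 0.05 to 0.54) and 1.42 in DRF (1.18 to 1.64), with a DRF peak at ZT22.9. Cpt1a (12894, chromosome 19, 3322326 to 3385735), which admits fatty acids to mitochondria, peaked at ZT9.46 in NRF and ZT21.9 in DRF (adjusted p of the difference 2.15e-08). Of the FoxO and atrophy genes, which include ligases and autophagy genes of protein breakdown, 9 of 20 differed, and 14 adjusted over the list alone (adjusted p = 0.0042). The ubiquitin ligase Fbxo32 (67731, chromosome 15, 58175879 to 58214892) had a peak-to-trough of 1.20 in NRF and 2.75 in DRF (adjusted p of the difference 0.0147). Another ligase gene, Fbxo21, peaked at ZT11.7 in NRF and ZT0.746 in DRF (3.24e-07).

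Lipid storage and synthesis genes differed as well. The adipocyte score had its own rhythm in NRF, with a peak at ZT13, and the list tests below were not rerun with it as a covariate. In the lipid droplet and lipolysis list 6 of 14 differed, and 10 adjusted over the list alone (adjusted p = 0.0308, and 0.18 with the gene-length trend removed). The droplet coat gene Plin5 (66968, chromosome 17, 56111597 to 56117606) had a peak-to-trough of 2.39 in DRF and 0.44 in NRF (adjusted p of the difference 0.00618, and 0.0534 on log2 of the deposited value plus 1), and the lipase gene Lipe peaked at ZT10.0 in NRF and ZT22.1 in DRF (1.55e-05). Of the fatty acid synthesis genes 7 of 18 differed, and 9 adjusted over the list alone (adjusted p = 0.0308). Gpam, which starts triglyceride assembly, peaked at ZT11.7 in NRF and ZT1.57 in DRF, and the desaturase Scd2 had a peak-to-trough of 1.29 in DRF, with a peak at ZT9.17 in the light phase. Cholesterol synthesis had the largest share, 11 of 19, and 12 adjusted over the list alone (adjusted p = 0.000137). Its score peaked at ZT3.33 in NRF and ZT8.16 in DRF, a difference of 4.83 h (95% interval 2.78 to 6.83).

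**Figure D2:**
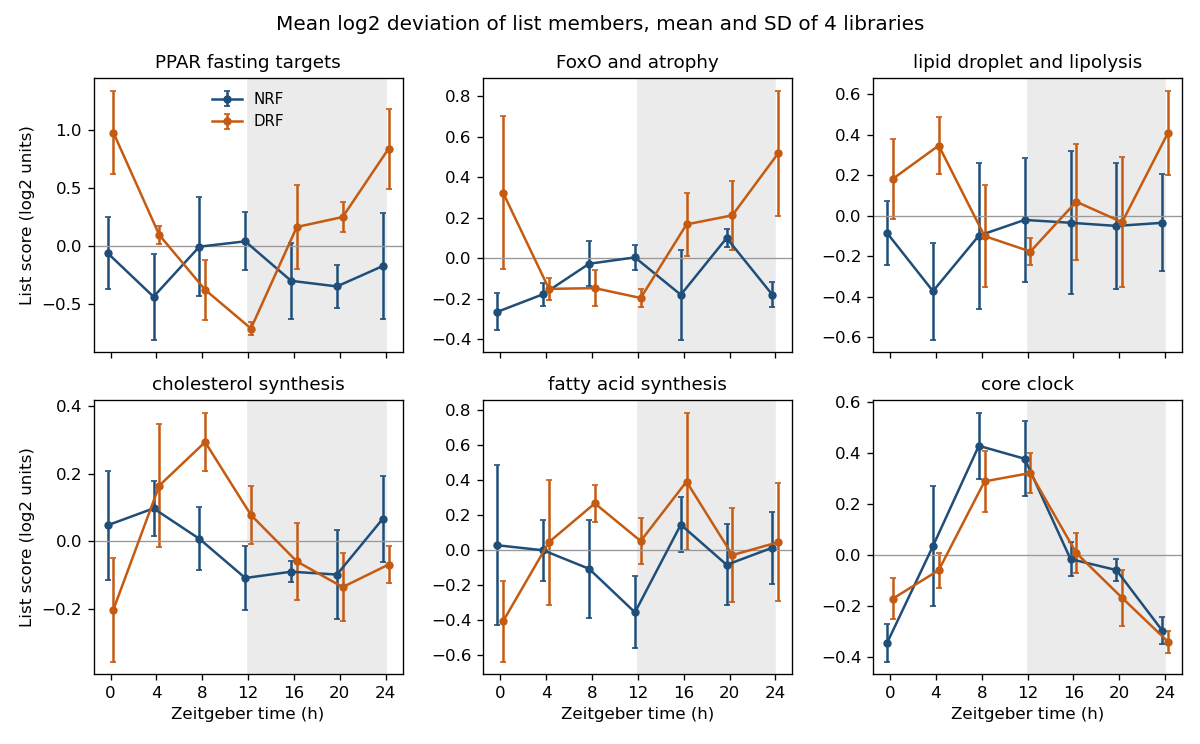
List score (log2 units, mean and SD of 4 libraries) of 6 gene lists against zeitgeber time in hours, NRF in blue and DRF in orange, with the dark phase shaded. The PPAR fasting targets have a fitted peak-to-trough of 1.42 in DRF and 0.21 in NRF, while the core clock scores peak at ZT10.3 in NRF and ZT10.5 in DRF.

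Other metabolic lists did not stand apart from other genes in this test. Among fatty acid uptake and oxidation genes 3 of 24 differed, also adjusted over the list alone (adjusted p = 1.0), although 18 passed the rhythm test in DRF and 0 in NRF (0 also at an unadjusted p in limma). Mlycd, which removes malonyl-CoA, and Acot2, a thioesterase whose decimal counts make it uncertain, were 2 of the 3, with DRF peak-to-trough values of 1.26 and 2.35. Glycolysis and glycogen genes differed in 3 of 23 cases, also adjusted over the list alone (adjusted p = 1.0). One was Ppp1r3c, a glycogen-targeting subunit that fell from a peak-to-trough of 2.84 in NRF to 1.56 in DRF (adjusted p of the difference 0.0204, and 0.0509 without ZT24). Oxidative phosphorylation genes differed in 0 of 23 cases in limma, with 0 at an unadjusted p (Fisher's exact test, adjusted p = 0.235).

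The next question was how many genes were rhythmic in each regimen. Dbp, a clock output gene that shares reads with other genes by its decimal counts, had the largest rhythm in NRF, with a peak-to-trough of 4.62 log2 units (24.6-fold) at ZT10.5, and 4.26 at ZT10.9 in DRF. Genes with large rhythms in both regimens included Angptl7, a secreted protein gene (3.46 in NRF and 2.08 in DRF), Odf3l2 (3.30 and 3.02), and Fkbp5 (14229, chromosome 17, 28398753 to 28486149), a glucocorticoid-induced chaperone gene (2.92 and 2.40). The rhythm test passed for 1820 genes in NRF (15.1%) and 5859 in DRF (48.7%), and for 1127 in both, where independent lists of these sizes would share 887. Many DRF rhythms were small. The median peak-to-trough was 0.46 log2 units over the NRF genes and 0.38 over the DRF genes, and 207 and 262 genes reached 1 log2 unit. Of the 4732 genes past the test in DRF and not in NRF, 910 passed the test of the difference. Libraries also differed in a trend with gene length. The Spearman correlation of a library's deviation with gene length, taken across genes, which are not independent replicates, averaged 0.193 in NRF at ZT0, −0.200 in DRF at ZT16 and −0.190 in DRF at ZT20. With within-group components as covariates the counts were 3171 in NRF and 4761 in DRF. Library weights gave 2837 in NRF, and an added 12 h harmonic gave 2762.

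**Figure D3:**
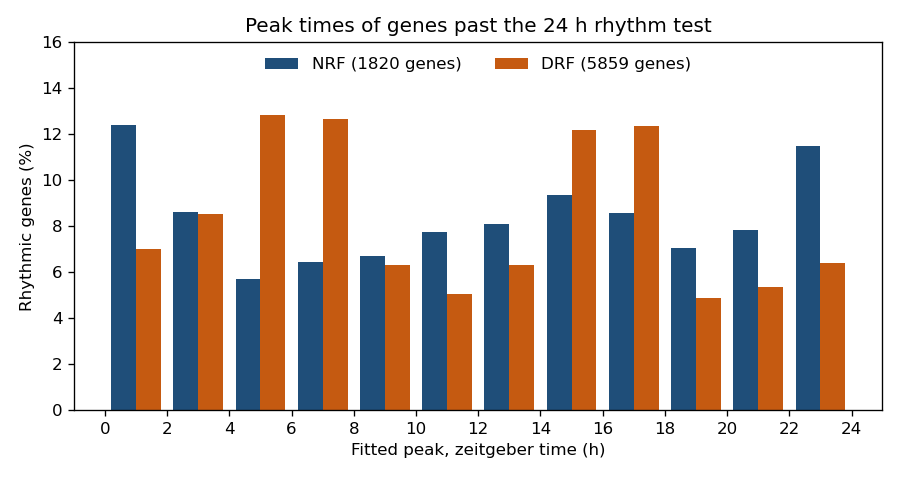
Share of rhythmic genes (%) by fitted peak in bins of 2 h of zeitgeber time, as bars for the 1820 NRF genes (blue) and the 5859 DRF genes (orange). DRF peaks gather at ZT4 to ZT6 (12.9%) and ZT16 to ZT18 (12.4%), and NRF peaks around lights on (11.5% at ZT22 to ZT24 and 12.4% at ZT0 to ZT2).

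The authors' deposited tables of rhythm tests listed 1154 NRF and 2557 DRF genes of 16119 at an adjusted p under 0.05. Among the genes tested here, 97.9% of the authors' NRF calls and 99.7% of their DRF calls passed the limma test too, and the phase differed by a median of 0.404 h in NRF and 0.321 h in DRF. In the other direction, only 1009 of 1820 limma calls in NRF and 2428 of 5859 in DRF were also the authors'. Independent lists of these sizes would share 156 and 1187. Both tests used the same libraries, so neither is an independent check of the other. In the authors' deposited table Per1 and Cry1 missed the threshold in DRF, with adjusted p-values of 1.0 and 0.302.

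The core clock was compared to ask whether the muscle's clock followed the food. Its phase stayed near that of NRF while the fitted 24 h peak-to-trough of several genes was smaller. Nr1d1 (217166, chromosome 11, 98767932 to 98775377, with decimal counts), a repressor of Arntl, peaked at ZT5.81 in NRF and ZT5.97 in DRF, and its peak-to-trough was 3.85 and 1.72 log2 units, a difference of −2.13 (95% interval −2.56 to −1.66, adjusted p of the rhythm difference 7.58e-05). Per1 (18626, chromosome 11, 69095108 to 69109965), a light and hormone responsive repressor, had 2.90 in NRF and 0.86 in DRF, a difference of −2.04 (−2.50 to −1.49, adjusted p = 0.0138, and up to 0.143 with ZT0 or ZT24 left out). It stood at 115 ± 10.6 CPM at ZT12 in NRF and 71.5 ± 13.8 in DRF, and at 14.5 ± 4.42 and 68.4 ± 14.1 at ZT0 (n = 4 each). Per1 was not flat in DRF, as it stood at 18.4 ± 8.31 CPM at ZT4 and 24.3 ± 15.8 at ZT20, between highs at ZT0 and ZT12 that a single 24 h cosine does not follow. Cry1 (12952, chromosome 10, 85131700 to 85185054), another repressor, had 1.12 and 0.39 (adjusted p = 0.000595) and peaked 2.09 h earlier in DRF (difference −2.09 h, −3.71 to −0.75). Its DRF rhythm passed the test but missed it without DRF ZT8 replicate 2 (adjusted p = 0.0577), DRF ZT8 replicate 3 (0.0577) or DRF ZT20 replicate 1 (0.0604). Arntl (11865, chromosome 7, 113178471 to 113314126), the activator of the loop, had 3.20 and 2.13 (difference −1.07, −1.44 to −0.68, adjusted p = 0.0279). Its call was lost without NRF ZT12 replicate 1 (0.0561), replicate 2 (0.0591) or replicate 3 (0.0556).

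Of the 19 core clock genes, 18 were rhythmic in NRF and 17 in DRF, and 4 differed, also adjusted over the list alone (Fisher's exact test, adjusted p = 0.70). Of the 17 rhythmic in both, 16 peaked within 2 h of their NRF time, and the median difference over those tested was −0.00404 h. The peak-to-trough was smaller in DRF for 16 of 19, with an interval below 0 for 10. Hlf, an output gene, was the 1 gene with an interval above 0 (difference 0.42, 0.13 to 0.68). Peak intervals excluded 0 for Npas2 (−0.64 h), Cry1 and Bhlhe40 (1.45 h). Rora passed the rhythm test in neither regimen. Over the 1127 genes rhythmic in both regimens the mean peak difference was −0.293 h (SD over 100 bootstrap resamples 0.331 h), 47.7% peaked within 2 h and 8.52% were 8 h or more apart. This is a description of genes, which are not independent replicates.

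**Figure D4:**
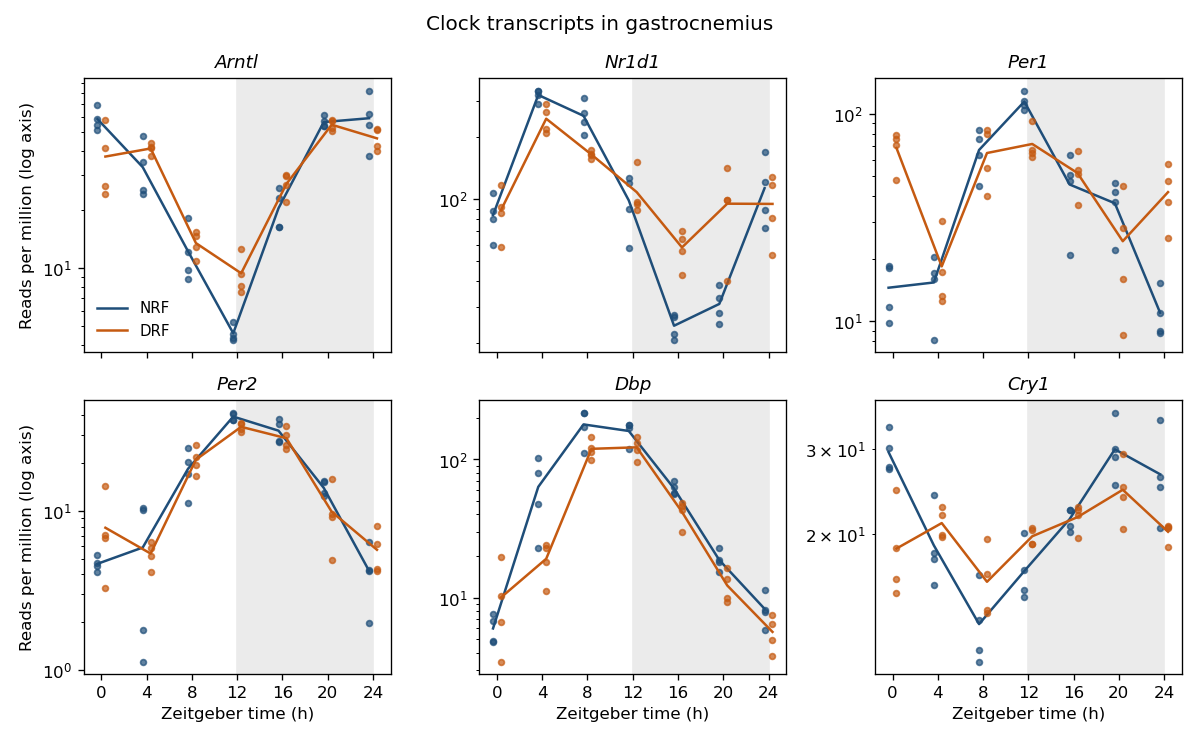
CPM (log axis) of 6 clock transcripts against zeitgeber time in hours, with a point per library, lines through the group means (NRF blue, DRF orange) and the dark phase shaded. Fitted peaks of most lie at similar times in both regimens, while Per1 in DRF has 2 highs, 68.4 CPM at ZT0 and 71.5 at ZT12, with 18.4 at ZT4 and 24.3 at ZT20, and in NRF runs from 11 at ZT24 to 115 at ZT12.

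The average over the day was compared to find transcripts whose level, apart from its timing, went with the regimen. Red blood cell genes and single genes such as cardiac actin were higher in DRF. Actc1 (11464, chromosome 2, 114047282 to 114052875), cardiac actin, was 0.87 ± 0.17 log2 units higher (SE, 28 libraries per regimen, 1.83-fold, adjusted p = 0.00115), and skeletal actin Acta1 was 0.29 ± 0.07 higher (0.00464, and up to 0.361 with quantile scaling or no filter). Both have decimal counts and are uncertain. Dmpk (13400, chromosome 7, 19083646 to 19093821), a muscle kinase, was 0.31 ± 0.05 higher (8.83e-05), and Fbp2, a muscle gluconeogenic enzyme, 0.28 ± 0.08 (0.0125, and 0.051 with the gene-length trend removed). All 5 red blood cell genes were higher, also adjusted over the list alone. Hbb-bs (chromosome 7, 103826523 to 103827928) rose by 0.57 ± 0.13 (0.0045) and Hba-a1 (chromosome 11, 32283672 to 32284486) by 0.55 ± 0.13 (0.00616), both with decimal counts. The camera adjusted p of the list was 0.000445, and the adjusted p was 0.65 with an estimated correlation. Lower in DRF were Zbed6 (667118, chromosome 1, 133655879 to 133660885), a repressor of Igf2, by −0.43 ± 0.11 (0.00751), the interferon-inducible genes Gbp7 (229900, chromosome 3, 142530336 to 142550151) by −0.42 ± 0.11 (0.0112), Ifit2 by −0.35 ± 0.10 (0.0132) and Parp14 by −0.28 ± 0.08 (0.0137), and Hlf by −0.29 ± 0.07 (0.00707).

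In all, 1909 genes differed on average (15.9%), 1004 higher and 905 lower in DRF. With within-group components as covariates 881 differed (474 higher and 407 lower), and the calls of Zbed6, Gbp7, Ifit2 and Parp14 ended (adjusted p = 0.0572, 0.136, 0.123 and 0.0957). Total-count scaling, which moved the median of all genes by −0.07 log2 units, gave 196 higher and 3302 lower, log2 of the deposited value plus 1 gave 375 and 637, and leaving out 1 library gave 1269 (without NRF ZT20 replicate 3) to 2917 (without NRF ZT20 replicate 4).

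Camera called 9 of 26 lists on average over the day, all upwards in DRF, and 0 with an estimated correlation (0 at an unadjusted p). Of the FoxO and atrophy genes 8 of 20 differed, each of them higher, and 9 adjusted over the list alone (adjusted p = 0.65 with an estimated correlation). Eif4ebp1, a brake on translation, rose by 0.24 ± 0.05 log2 units (adjusted p = 0.00117) and Sqstm1, an autophagy receptor gene, by 0.19 ± 0.05 (0.00497). Of the glycolysis and glycogen genes 8 of 23 were higher and 1 lower, the same counts as adjusted over the list alone (adjusted p = 0.65 with an estimated correlation), among them Pgk1 (0.20 ± 0.04) and Pgam2 (0.26 ± 0.06). Lipid droplet and lipolysis genes were higher in 4 cases and lower in 1 of 14, 5 and 1 adjusted over the list alone (adjusted p = 0.65 with an estimated correlation). Among them Pnpla2, the first lipase of stored fat, rose by 0.36 ± 0.10 (adjusted p = 0.0162, and up to 0.0604 in other settings). Fatty acid uptake and oxidation genes were higher in 3 of 24 cases, 2 adjusted over the list alone (adjusted p = 0.68 with an estimated correlation), and oxidative phosphorylation genes in 3 of 23, 1 adjusted over the list alone (adjusted p = 0.68 with an estimated correlation). Fatty acid synthesis had 1 of 18 higher under either adjustment and endoplasmic reticulum stress 2 of 12, 4 adjusted over the list alone (adjusted p = 0.65 with an estimated correlation for each). Fast fibre genes were higher in 2 of 12 cases, 5 adjusted over the list alone (adjusted p = 0.65 with an estimated correlation). Slow fibre genes differed in 0 of 9 cases in limma, with 0 adjusted over the list alone, 0 at an unadjusted p and a median of 0.02. The slow fibre score itself ranged from −4.26 in DRF ZT20 replicate 2 to 1.58 in DRF ZT0 replicate 3, a 57.3-fold range between pieces of muscle.

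At the single times the question was when in the day the regimens parted. At the end of the dark phase, in which DRF mice were not fed, members of the FoxO and atrophy list and of the PPAR fasting targets were higher, gene by gene. At ZT24, Arrdc2 was 3.57 ± 0.51 log2 units higher in DRF (SE, adjusted p = 3.3e-05), Angptl4 3.40 ± 0.56 (0.00015) and Depp1 (213393, chromosome 6, 116650684 to 116652847), a FoxO-regulated gene, 3.29 ± 0.54 (0.00015). Depp1 stood at 58.1 ± 34.2 CPM in DRF and 3.69 ± 1.13 in NRF (n = 4 each). Igf1 (16000, chromosome 10, 87858265 to 87937047), a growth factor of muscle, was lower by −1.14 ± 0.24 (0.0025), at 12.6 ± 4.98 against 28.3 ± 7.51 CPM, and Auts2 by −1.21 ± 0.20 (0.00016). Of the FoxO and atrophy genes 14 of 20 were higher at ZT24, 18 adjusted over the list alone (adjusted p = 0.0795 with an estimated correlation). At ZT0, Arrdc2 (3.45 ± 0.51, adjusted p = 0.00014) and Chac1 (2.90 ± 0.45, 0.00014) were higher, and Igfbp5 (16011, chromosome 1, 72858065 to 72874865), a binding protein of insulin-like growth factors, was lower by −1.37 ± 0.26 (0.0025). Pdk4 was 3.45 ± 0.76 higher at ZT0 (0.0077, and 0.0549 without DRF ZT0 replicate 1). Of the PPAR fasting targets 5 of 14 were higher at ZT0, 9 adjusted over the list alone (adjusted p = 0.0963 with an estimated correlation), and 7 of 14 at ZT24, 8 adjusted over the list alone (adjusted p = 0.315 with an estimated correlation).

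Inside the light phase, where DRF mice ate, other genes parted. At ZT4, G0s2 was 2.71 ± 0.45 higher in DRF (adjusted p = 0.00078), at 61.2 ± 9.98 against 8.75 ± 2.70 CPM, and Acot2, with decimal counts, 2.60 ± 0.46 (0.0016). Heat shock genes were higher in 2 of 15 cases at ZT4, 7 adjusted over the list alone (adjusted p = 0.0795 with an estimated correlation). At ZT8, Lonrf3 was 1.17 ± 0.22 higher (0.0055, and 0.0797 without NRF ZT8 replicate 4). Pnpla3, a lipid droplet acyltransferase and hydrolase, was 1.33 ± 0.27 higher (0.012), at 22.8 ± 1.19 against 8.72 ± 2.94 CPM, and its call ended without NRF ZT8 replicate 1 (0.0542), replicate 2 (0.0632) or replicate 4 (0.0797). Cholesterol synthesis genes passed singly in 0 of 19 cases at ZT8 in limma (9 at an unadjusted p) and 8 were higher adjusted over the list alone (adjusted p = 0.0795 with an estimated correlation). At ZT12, the end of the light phase, Pck1 was lower by −2.94 ± 0.57 (0.0033), at 1.09 ± 0.685 against 17.1 ± 11.6 CPM. The mean adipocyte score at ZT12 was −0.55 ± 0.48 in DRF and 0.50 ± 0.63 in NRF, and 2 of 8 adipocyte genes were lower under either adjustment (adjusted p = 0.708 with an estimated correlation). Cited4, a transcriptional coactivator gene, was 1.35 ± 0.27 higher (0.0043). Pdk4 was lower at ZT12 by −3.27 ± 0.76 (0.014), a call lost without DRF ZT12 replicate 1 (0.0592) or NRF ZT12 replicate 3 (0.0501). Of the PPAR fasting targets 5 of 14 were lower at ZT12, and 7 were lower and 1 higher adjusted over the list alone (adjusted p = 0.37 with an estimated correlation).

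In the dark phase the atrophy-related gene Klhl38 was 1.47 ± 0.32 higher in DRF at ZT16 (adjusted p = 0.0094) and Nr1d1 1.47 ± 0.27 higher at ZT20 (0.0014). Ucp3 was 1.58 ± 0.38 higher at ZT20 (0.016, and 0.0633 without NRF ZT20 replicate 2). Lower at ZT16 were Lrrcc1 (−1.19 ± 0.25, 0.0077) and Zfp62 (−1.09 ± 0.25, 0.013), and both calls ended without DRF ZT16 replicate 3 (0.0536 and 0.09). Of the red blood cell genes 4 of 5 were higher at ZT16, 5 adjusted over the list alone (adjusted p = 0.502 with an estimated correlation).

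The counts over all genes, higher and lower in DRF, were 106 and 116 at ZT0, 81 and 36 at ZT4, 13 and 12 at ZT8, 258 and 163 at ZT12, 483 and 810 at ZT16, 86 and 270 at ZT20, and 421 and 248 at ZT24. They rested on single libraries, as 65 differed at ZT0 without DRF ZT0 replicate 1, 39 at ZT4 without NRF ZT4 replicate 4, 7 at ZT8 without NRF ZT8 replicate 4, 51 at ZT12 without DRF ZT12 replicate 1, 40 at ZT16 without DRF ZT16 replicate 3, 60 at ZT20 without NRF ZT20 replicate 3 and 267 at ZT24 without DRF ZT24 replicate 4, and within-group components as covariates left 50 at ZT16. Total-count scaling, which moved the median of all genes by −0.12 log2 units at ZT0, −0.16 at ZT12 and −0.11 at ZT16, gave 49 and 483 at ZT0, 24 and 42 at ZT4, 80 and 660 at ZT12, 34 and 2002 at ZT16, 35 and 290 at ZT20, and 149 and 345 at ZT24, quantile scaling gave 108 and 127 at ZT20, and log2 of the deposited value plus 1 gave 338 and 116 at ZT12, 59 and 409 at ZT16, and 43 and 315 at ZT20. Of the 42 genes named at the single times by rule, 15 passed with every library left out in turn and 27 missed in at least 1. Camera called 60 of 182 tests of lists at single times, and 0 with an estimated correlation (22 at an unadjusted p).

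ZT24 was compared with ZT0, the same clock time, to ask how far each series closed on itself. In DRF the activity and stress responsive genes Slc25a25, Sik1 and Nr4a1 were lower at ZT24 than at ZT0. Slc25a25, a mitochondrial carrier gene with decimal counts, stood at 203 ± 56.7 CPM at ZT0 and 28.1 ± 22 at ZT24 (n = 4 each), a difference of −3.05 ± 0.60 log2 units (adjusted p = 0.022). Inmt, a methyltransferase gene, went from 8.50 ± 3.43 to 19.7 ± 4.34 CPM (1.18 ± 0.22, 0.011). In all, 33 genes differed in DRF, 13 higher and 20 lower at ZT24, and 0 in NRF in limma (934 at an unadjusted p). The DRF count was 0 without DRF ZT0 replicate 4 (limma) and 112 without DRF ZT0 replicate 1, quantile scaling gave 46 higher and 39 lower, and total-count scaling 1 and 5. The 10 genes named here by rule each lost their call without at least 1 library. Slc25a25 did so without DRF ZT0 replicate 3 (0.109), DRF ZT0 replicate 4 (0.0888), DRF ZT24 replicate 1 (0.0558) or DRF ZT24 replicate 3 (0.0648), and Inmt without DRF ZT0 replicate 4 (0.0966), DRF ZT24 replicate 1 (0.0601) or DRF ZT24 replicate 3 (0.0534).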

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

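The corrections for gene length, slow-fibre content, within-group components and adipose tissue and the blood marker sets were chosen after the patterns were seen, and the test on other red-cell genes after part of its result. The rhythm of 1578 genes differed between DRF and NRF by a test of the difference itself (F test in limma). By adjusted p this held for Pdk4 (1.77e-06), Angptl4 (2.09e-05), Ucp3 (2.57e-08), Chac1 (0.000133), Pck1 (0.00165), G0s2 (0.000623), Pfkfb3 (0.000117), Slc25a34 (0.00329), Cyp2e1 (0.00283) and Arrdc2 (0.0157), and for the clock genes Arntl (0.0279), Per1 (0.0138), Cry1 (0.000595) and Nr1d1 (7.58e-05). The Arrdc2 and Per1 calls ended with ZT0 or ZT24 left out (up to 0.232 and 0.143), and the Arntl call without NRF ZT12 replicate 1 (0.0561), replicate 2 (0.0591) or replicate 3 (0.0556). In the lists, 6 lipid droplet and lipolysis genes, 8 PPAR fasting targets, 9 FoxO and atrophy genes, 7 fatty acid synthesis genes and 11 cholesterol synthesis genes differed.

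Other splits of the samples show which of these counts chance could give. They argue against chance for the rhythm difference (1578 genes, highest other split 83, with 1 of 100 splits as large, the real one), the average over the day (1909 against 0 in limma, 1 of 100), the NRF rhythm (1820 against 219, 1 of 100) and the DRF rhythm (5859 against 1047, 1 of 100). A share of 1 in 100 is the smallest that 100 splits can give, and it was read without correction for the number of counts. The splits also take each library as a separate unit, which the labels do not state. For the lists that differ in rhythm (5 against 1, 1 of 100) the splits cannot decide. The other splits called a median of 0 genes with a rhythm difference in limma, so hardly any list could pass in them. At ZT0 (222 against 30), ZT4 (117 against 1), ZT16 (1293 against 1) and ZT24 (669 against 251) only the real split, 1 of 35, was as large. That is the smallest share 35 splits can give, and it was read at each time without correction for the number of comparisons. The splits therefore argue against chance at these times but do not exclude it at any 1 of them. Nor can chance be excluded at ZT8 (25 against 116, 2 of 35), ZT12 (421 against 961, 2 of 35) and ZT20 (356 against 1706, 6 of 35), or for ZT24 against ZT0 in DRF (33 against 114, 2 of 35). For ZT24 against ZT0 in NRF the real count was 0 (limma, 934 at an unadjusted p, highest other split 1), so 35 of 35 splits were bound to be as large and the splits say nothing about chance. At ZT8, at ZT20 and for ZT24 against ZT0 in DRF a split other than the real one called several times as many genes, which points to a structure of these samples other than the groups compared. Chance cannot be excluded either for camera's list calls on average (9 against 15, 35 of 100) or at single times (60 against 74, 25 of 100).

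More genes were rhythmic in DRF (5859) than in NRF (1820), a ratio of 3.22 (2.71 without DRF ZT20 replicate 1 to 3.58 without NRF ZT16 replicate 3), with 5882 and 1831 after median-ratio scaling, 5821 and 1966 after quantile scaling, 6284 and 2837 with library weights, and 5791 and 2762 with a 12 h harmonic. A trend with gene length that differs between libraries is argued against as the whole cause, because the ratio was 2.96 with the trend removed (2.52 to 3.26 with 1 library left out), and slow-fibre content is too, because the ratio was 2.56 with that score as a covariate (2.02 to 2.83). Variation shared by libraries within groups stays open, since with the within-group components as covariates (29.4% and 13.8% of the within-group variance) the ratio was 1.501 (1.37 without DRF ZT20 replicate 3 to 1.65 without NRF ZT12 replicate 2), at the limit of 1.5 set for it. Component 2, whose loadings had a Spearman correlation of 0.323 in size with gene length across genes, which are not independent replicates, was lowest in DRF at ZT16 (−1.30 ± 1.14) and ZT20 (−0.94 ± 1.52), so this covariate may remove part of a regimen effect as well. The feeding regimen itself, which the design names, is another candidate explanation and was not tested.

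The rhythm of the PPAR fasting targets differed between the regimens in 8 of 14 genes. Adipose tissue in some pieces is argued against as the whole cause, because 100% of these 8 genes still differed with the adipocyte score as a covariate. Slow-fibre content is argued against in the same way (100% still differed with that score as a covariate, and 9 of the 14 in all), and 10 of the 14 differed with the within-group components as covariates. The feeding regimen itself stays open as a candidate explanation and was not tested apart from these.

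Haemoglobin transcripts were higher in DRF by a mean of 0.55 log2 units (95% interval 0.32 to 0.79, 4 of 4 genes), by 0.47 with the gene-length trend removed and by 0.49 with within-group components as covariates. Whole blood left in the pieces stays open although white-cell genes did not rise with them (mean difference −0.017, −0.19 to 0.16, 3 of 6 tested genes below 0), and although the limit written beforehand would have ruled it out. That limit assumed that the white-cell transcripts of these pieces come from blood alone, but cells resident in muscle make Cd74 (62.6 CPM) and the 5 others tested (1.64 to 11.6 CPM, differences of −0.15 to 0.05) as well, no blood sample here gives the level that blood would add, and S100a8 and S100a9 (0.066 and 0.13 CPM) were too low to test. More immature red cells may also contribute and stay open, as other red-cell genes were higher by a mean of 0.16 (0.10 to 0.23, 3 of 7 genes tested), but by 0.06 without Alas2 (−0.01 to 0.13), whose rise had been seen before. The other genes tested, Bpgm (110 CPM) and Fech (188 CPM), missed the limma threshold (adjusted p = 0.37 and 0.31). They stood far above Alas2 (5.41 CPM), while haemoglobin genes stood at 22.8 to 182 CPM, so their reads need not come from red cells. These explanations cannot be told apart, and an effect of the feeding regimen on red cells was not tested.

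In some groups 1 library lay far from the other 3, by a gap to its nearest neighbour that, over the range of the group, was above Dixon's 95% critical value for 4 samples. This held in 5 of 53 groups of gene levels and 8 of 140 groups of list scores, where chance gives about 1 in 20. Among gene levels it was Ucp3 in NRF ZT0 replicate 1 (gap over range 0.868, 159 CPM against a median of 54.8), Arrdc2 in DRF ZT0 replicate 1 (0.848, 162 against 68.8), Per1 in DRF ZT12 replicate 3 (0.833, 92.0 against 66.0), and Pnpla3 in NRF ZT8 replicate 3 (0.861, 13.1 against 7.44) and DRF ZT8 replicate 1 (0.839, 21 against 23.3). Among scores it was slow fibre in DRF ZT0 replicate 3 (0.902) and NRF ZT4 replicate 3 (0.833), red blood cell in DRF ZT12 replicate 3 (0.882), macrophage and leukocyte in DRF ZT20 replicate 4 (0.838), nerve and Schwann cell in DRF ZT0 replicate 2 (0.894) and DRF ZT12 replicate 1 (0.924), and fast fibre in DRF ZT4 replicate 1 (0.853) and DRF ZT8 replicate 3 (0.851).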

How the results depend on the processing

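Of 334 named gene results, 213 were past the limma threshold, and only such calls could count as reversed. The 56 called rhythm differences among them could not, as no direction was set for them. Of the other calls, 0 reversed in the alternatives run for them. A reversal was a change of sign or, for a rhythm, a large shift of peak past the threshold in both fits. Of those 213, 150 stayed past it with each library left out in turn and 130 in every other setting run for them. Some settings apply to part of these results, and the 12 h harmonic, the F tests over the 7 times and the authors' adjusted p are not among them. In simulated data, 16.4% of differences of 0.25 log2 units were recovered at ZT16, 55.2% of 0.5 and 93.9% of 1, and on average over the day 71.6%, 97.0% and 98.5%, so small single-time differences are often missed. Depth was not varied in these simulations, and each gene was drawn independently. Variation shared across genes within a library was left out, so these shares need not hold for the real libraries. Log2 of the deposited value, total-count scaling, the slow-fibre covariate, gene-length removal, within-group components and leaving out the 2 outlying libraries were chosen after seeing the data. The main counts were 1909 on average, 1820 (NRF) and 5859 (DRF) for rhythm, 1578 for the rhythm difference, 222, 117, 25, 421, 1293, 356 and 669 at ZT0 to ZT24, and 0 and 33 for ZT24 against ZT0 in NRF and DRF. A setting not named for a count left it within 1.5 times. Where a setting drops libraries or times, fewer samples entered the test, and for the other changes below the cause was not tested.

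Quantile scaling gave 235 at ZT20 and 85 for DRF ZT24 against ZT0. Library weights gave 1072 at ZT0, 531 at ZT4, 57 at ZT8, 1358 at ZT12, 2484 at ZT16, 660 at ZT20, 1263 at ZT24, 135 and 266 for ZT24 against ZT0 in NRF and DRF, 2837 for the NRF rhythm and 2687 for the rhythm difference. Without ZT24 the average gave 1058 and the rhythm difference 1017, and a 12 h harmonic gave 2762 for the NRF rhythm. The authors' adjusted p gave 1154 in NRF and 2557 in DRF over their 16119 genes, and 1031 and 2436 among the 12025 genes tested here. With an estimated correlation camera called 0 lists on average and 0 at single times (0 and 22 at an unadjusted p). Log2 of the deposited value plus 1 gave 1012 on average, 143 at ZT0, 69 at ZT4 and 468 at ZT16. Total-count scaling gave 3498 on average, 532 at ZT0, 66 at ZT4, 740 at ZT12, 2036 at ZT16 and 6 for DRF ZT24 against ZT0. The slow-fibre score as a covariate gave 2400 for the rhythm difference, 428 at ZT0, 38 at ZT8, 1216 at ZT20, 1124 at ZT24 and 113 for DRF ZT24 against ZT0. With the gene-length trend removed, 1048 differed on average and 122 at ZT20 (50 higher and 72 lower). Within-group components as covariates gave 881 on average, 3171 for the NRF rhythm, 2592 for the rhythm difference, 821 at ZT0, 318 at ZT4, 161 at ZT8, 213 at ZT12, 50 at ZT16, 1758 at ZT20, 1308 at ZT24, and 27 and 244 for ZT24 against ZT0 in NRF and DRF. Without the 2 outlying libraries (DRF ZT20 replicate 1 and NRF ZT12 replicate 3) the counts were 995 on average, 68 at ZT12, 2033 at ZT16, 145 at ZT20, 1072 at ZT24 and 309 for DRF ZT24 against ZT0.

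With 1 library left out the counts ran from 1269 (without NRF ZT20 replicate 3) to 2917 (NRF ZT20 replicate 4) on average, 1626 (NRF ZT16 replicate 3) to 1910 (NRF ZT4 replicate 3) for the NRF rhythm, 4979 (DRF ZT16 replicate 3) to 5976 (DRF ZT8 replicate 3) for the DRF rhythm, and 1370 (NRF ZT12 replicate 2) to 2208 (NRF ZT20 replicate 4) for the rhythm difference. At single times they ran from 65 (DRF ZT0 replicate 1) to 243 (DRF ZT0 replicate 4) at ZT0, 39 (NRF ZT4 replicate 4) to 149 (NRF ZT4 replicate 1) at ZT4, 7 (NRF ZT8 replicate 4) to 29 (NRF ZT8 replicate 3) at ZT8, 51 (DRF ZT12 replicate 1) to 1118 (NRF ZT12 replicate 4) at ZT12, 40 (DRF ZT16 replicate 3) to 1998 (DRF ZT16 replicate 4) at ZT16, 60 (NRF ZT20 replicate 3) to 967 (NRF ZT20 replicate 4) at ZT20, and 267 (DRF ZT24 replicate 4) to 1087 (DRF ZT24 replicate 2) at ZT24. For ZT24 against ZT0 they ran from 0 (DRF ZT0 replicate 4) to 112 (DRF ZT0 replicate 1) in DRF and stayed at 0 in NRF (limma).

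With the replicate number as a block the counts were 1803 on average, 1760 and 5751 for the NRF and DRF rhythm and 1483 for the rhythm difference. The numbers do not pair the samples, since the deviations of 364 same-number pairs had a mean correlation of −0.017 (120 over 0.1), those of 1092 different-number pairs 0.0058, and 8 of 56 libraries were closest on average to those of their own number. The mean peak difference of −0.293 h became −0.188 h without ZT24 and −0.541 h with a threshold of 0.001, within its spread of 0.331 h. The lists past the Fisher test for rhythm numbered 5, with 4 after gene-length removal (lipid droplet and lipolysis lost, adjusted p = 0.18), 7 with the slow-fibre covariate (ribosome biogenesis 0.0298 and oxidative phosphorylation 0.0311 added), and 5 with the block. The Fisher test is two-sided, and without the covariate 0 of 23 oxidative phosphorylation genes differed, against 13.1% of other genes. The passing of that list therefore cannot be read as more of its members differing.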

Other observations

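The interferon set was chosen as a test only after genes of this kind were seen among the lower ones. For 5 of 7 stress and hormone responsive lists the score peaked at another time in DRF, by intervals that exclude 0. The share of members whose rhythm differed was 16.7% to 33.3% in these lists, against 13.1% of other genes, and passed Fisher's exact test for none of them after adjustment. Several scores were nearly flat, so their peak times say little. In NRF and DRF the peak-to-trough was 0.14 and 0.08 log2 units for endoplasmic reticulum stress (2 and 2 of 12 members rhythmic). It was 0.16 and 0.17 for ribosome biogenesis (2 and 7 of 16) and 0.19 and 0.22 for amino acid response (5 and 3 of 16). Heat shock had 0.39 and 0.36 (3 and 7 of 15), and glucocorticoid targets 1.13 and 0.81. Of 13 glucocorticoid targets, genes that follow corticosterone, 12 were rhythmic in NRF and 10 in DRF, and 3 differed, 7 adjusted over the list alone (Fisher's exact test, adjusted p = 0.693). Their score peaked at ZT16.2 in NRF and ZT19.3 in DRF, 3.11 h later (95% interval 1.66 to 4.53). Mt1, a metallothionein gene, moved from ZT16.2 to ZT20.5 (adjusted p of the difference 0.00952, and 0.0555 without ZT24), and Glul, glutamine synthetase, from ZT15.8 to ZT17.9 (0.0099, and 0.159 without ZT24). Heat shock genes differed in 3 of 15 cases, 7 adjusted over the list alone (0.699), and their score peaked at ZT21.1 in NRF and ZT4.51 in DRF, 7.44 h apart (5.18 to 9.43). The chaperone gene Dnaja1 (15502, chromosome 4, 40722468 to 40734965) peaked at ZT20.7 in NRF and ZT7.96 in DRF (0.000274), and Hsp90aa1 peaked at ZT5.85 in DRF with a peak-to-trough of 1.00 (0.00216). Ribosome biogenesis genes differed in 5 of 16 cases under either adjustment (0.211), with score peaks at ZT14.9 and ZT5.97, a difference of −8.92 h (−11.4 to −5.96), and Rrs1, a ribosome assembly gene, had a DRF peak-to-trough of 0.72 at ZT1.18 (0.00257). Of the endoplasmic reticulum stress genes 2 of 12 differed under either adjustment (0.864), and the score moved from ZT18.7 to ZT9.74 (−8.95 h, −13 to −4.20). The cochaperone gene Dnajb9 had a peak-to-trough of 0.46 in NRF at ZT14.6 and 0.17 in DRF (3.64e-05). Amino acid response genes differed in 3 of 16 cases under either adjustment (0.699), with score peaks at ZT13.5 and ZT18.8 (5.35 h, 3.08 to 7.44). Of the immediate early genes 3 of 14 differed, 5 adjusted over the list alone (0.699), among them Junb (0.00606) and Jun, which moved from ZT16.4 to ZT21.2 (0.0131, and up to 0.0921 with ZT0 or ZT24 left out), and the interval of the score's peak difference spanned 0 (−5.27 h, −16.6 to 5.94). Of the 3 cold-inducible genes 1 differed under either adjustment (0.699), the splicing factor gene Srsf5 (0.0172, and up to 0.0871 in other settings), and the score's interval spanned 0 as well (−4.11 h, −14.7 to 6.61).

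Cell type lists were compared in the same way. The satellite cell score, from genes of muscle stem cells, had a peak-to-trough of 0.58 in NRF and 0.09 in DRF, a difference of −0.49 (95% interval −0.64 to −0.32). The score is a mean over 6 members, of which only 2 passed the rhythm test in NRF and 1 in DRF. It therefore does not show a rhythm of the list as a whole. Of the 6 members 1 differed in rhythm, 2 adjusted over the list alone (Fisher's exact test, adjusted p = 0.823). This was Myod1 (17927, chromosome 7, 46376474 to 46379092), a myogenic regulator, with a peak-to-trough of 2.22 in NRF at ZT20.4 and 0.91 in DRF at ZT17.4 (adjusted p of the difference 0.00196). In NRF Myod1 stood at 13 ± 1.26 CPM at ZT12 and 55.9 ± 5.61 at ZT16 (n = 4 each), and in DRF its means were high at both ZT4 and ZT16, which a single cosine does not follow. Of 10 endothelial genes 1 differed, 3 adjusted over the list alone (1.0), the tight junction gene Cldn5, with 0.60 at ZT2.41 in NRF and 1.64 at ZT22.4 in DRF (1.7e-05). Of 12 fast fibre genes 9 were rhythmic in DRF and 0 in NRF in limma (0 at an unadjusted p), with DRF values of 0.68 for Casq1, 0.69 for Pvalb and 0.61 for Mylpf, but 0 differed between the regimens (0 at an unadjusted p, Fisher's exact test, adjusted p = 0.699). Of 8 adipocyte genes 2 differed under either adjustment (0.699), Pck1 and the droplet gene Cidec, whose call (0.0497) was lost in 36 of 56 cases with 1 library left out (up to 0.105 without DRF ZT12 replicate 2). Slow fibre (9 tested), extracellular matrix (14), macrophage and leukocyte (10), red blood cell (5), brown adipocyte (2) and nerve and Schwann cell (6) genes differed in rhythm in 0 cases in limma (0 at an unadjusted p).

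Several interferon-inducible genes were lower in DRF on average over the day, and the hypothesis was that this may hold for the set. Over 35 interferon-inducible genes, without the 5 taken by the naming rule (Gbp3, Gbp7, Gbp9, Ifit2 and Parp14), the mean difference was −0.13 log2 units (95% interval −0.26 to −0.01), with 31 below 0, 4 past the threshold as lower and 1 as higher (Gbp10, 0.65 ± 0.18, adjusted p = 0.013). Over all 40 it was −0.16 (−0.29 to −0.03), with 9 lower and 1 higher, and 10 and 1 adjusted over the list alone. With within-group components as covariates the means were −0.06 and −0.08, and with the gene-length trend removed −0.14 and −0.16. The interval over the 35 genes lies below 0 but close to it, so the hypothesis passed this test only by a small margin. A bootstrap of 4 libraries per group tends to give too narrow an interval. The 35 genes were also measured in the same libraries as the 5 that prompted the test. Whether the set is lower in DRF therefore stays open.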
